A study of Mus musculus with 2 samples.

How the data were processed

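H3K9ac ChIP-seq peak lists from the forebrain of mouse embryos at embryonic day 11.5 were analysed, in 1 group of 2 biological replicates. Per the labels, the strain was B6NCrl, tissue of both sexes was pooled, and the assembly was mm10. Per the text files deposited with the lists, each replicate's list was called on that replicate's alignments, the pooled list on the alignments of both, and the replicated list was derived from the pooled list and both replicates' lists. The aligner, the peak caller, the filters and the thresholds are not given in the sources used here. The replicated list was checked to be a subset of the pooled list, with all 35463 peaks identical in every column.

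The deposited lists give for each peak a display score, which was not used, a fold enrichment of ChIP over control, which is a linear ratio, and a −log10 p and a −log10 q by the authors' caller. They also give the deposited offset of the summit from the peak start. Whether the fold enrichment is a summit value or a mean is not given in the sources used here. The lowest −log10 p in the deposited lists lay between 2.01 and 2.05. Fold enrichment was used to rank, filter or describe peaks, to correlate paired peaks of the replicates and to compare replicated with other pooled peaks. The lists hold no read counts, so depth is unknown and no interval that needs it is given. Because every list holds called peaks only, a gene without a peak is a gene without a call, and a weaker signal there would not be seen. Peaks of the pooled and replicated lists have no replicate error of their own. Wilson intervals (95%) cover counting error of genes or peaks only.

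Peaks were set against the GRCm38 genome sequence, the assembly that mm10 names, and the GENCODE M21 annotation, and chromosome names and lengths were compared before coordinates were used. Analyses used the standard chromosomes, and 8 peaks of each of replicate 1, replicate 2 and the pooled list and 6 of the replicated list on other scaffolds were left out. Peaks were assigned by midpoint to promoter (within 1000 bp of a TSS of a protein-coding or lncRNA gene), then exon, intron or intergenic sequence. A protein-coding gene was marked where a peak overlapped the 1000 bp on either side of any of its TSSs, so a peak between neighbouring genes can mark both. Breadth was the number of bases covered within 5000 bp on either side of the gene's most covered TSS, by any peak of the list, peaks of neighbouring genes included. Distal peaks had their midpoint more than 1000 bp from every TSS, so a broad peak that reaches over a TSS can be distal. They were assigned to the protein-coding gene with the nearest TSS, and a gene's territory was the sequence nearest to it. CpG content was counted over the 1000 bp on either side of the gene's outermost 5′ TSS only and divided into deciles. Marking could rest on any TSS, so the CpG content at the marked TSS of a gene can differ from the value used for matching.

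Peaks of the replicates were called shared where the overlap was at least 50% of either peak. Shares were compared with 1000 random placements on the same chromosome with widths kept. Lists of genes were compared with all other protein-coding genes by Fisher's exact test (two-sided) for marking, and by permutation tests with 100000 resamples (two-sided) for mean log2 breadth among marked genes, in lists with at least 5 marked members, and for distal peaks per gene, within deciles of territory length. Motif counts on both strands in 500 bp around the midpoint were compared with the mean of flanks whose centres lay 3000 bp to either side and overlapped no pooled peak, by a sign-flip permutation test with 100000 resamples. Marking at like CpG content was compared within deciles of CpG content. The planned Mantel-Haenszel test rests on an approximation, and because few unmarked genes were expected in some lists, an exact conditional test over the same deciles (two-sided) was added after the data were seen. The adjusted p values at like CpG content are those of the exact test unless Mantel-Haenszel is named. Each family of tests was adjusted by Benjamini-Hochberg, and an adjusted p of 0.05 was the threshold. Of 535 names in 22 fixed lists, 532 matched a protein-coding gene, and H19 and Meg3 (lncRNA genes) and Ahsp were left out. The other 3 of the 25 lists (olfactory receptors, cytosolic ribosomal proteins and replication-dependent histones) were defined by gene name patterns. Some genes are in 2 lists.

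The lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule takes from each list the 3 marked genes of highest fold enrichment and up to 3 unmarked genes in alphabetical order, the 10 genes with the most covered bases, the 10 distal peaks and the 5 peaks of highest fold enrichment, the 5 fixed-list genes with the most distal peaks, and up to 5 genes marked in 1 replicate only. Foxg1, Hoxd8 and other genes outside it were named after their values were seen. Alternatives were promoter windows of 500 and 2500 bp, a −log10 q of at least 2, the peaks with a fold enrichment of at least the list's median (4.99), the pooled list, each replicate's list alone, 1 TSS per gene, matching on CpG or GC content (within 5 percentage points), other overlap rules and windows, and, added after the data were seen, the exact test over CpG deciles and random positions outside assembly gaps. No test between the 2 samples was possible.

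The procedures were tested on simulated data. Overlap rules had 0 disagreements with a brute-force count in 3600 comparisons. In lists of 25 genes, the Fisher test called 98.5% of lists whose genes were marked with a raised probability and 2.5% of unchanged lists at a p under 0.05, over 21938 genes. The breadth test, over 14060 genes, called 80.5% of lists shifted by 0.5 on the log2 scale and 1.0% of unshifted lists. The exact test over CpG deciles had 0 disagreements with the Fisher test in a single stratum and called 1.5% of lists marked at their deciles' own rates, over 21938 genes. For distal peaks, lists of genes with long territories and no change were called in 5.5% of cases with strata and 30.5% without. The motif test called 2.0% of simulations with no implanted motif. Peaks and flanks had the same base composition there, unlike in the data (GC content 52.8% and 46.5%), so this rate does not cover calls that come from composition. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, numba 0.67.0, matplotlib 3.10.9 and samtools 1.23.1.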

Results

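Acetylation of histone H3 at lysine 9 (H3K9ac), a histone mark known from active promoters, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in the forebrain of mouse embryos at embryonic day 11.5. There was 1 group with 2 biological replicates. Replicate 1 held tissue pooled from 109 embryos of both sexes, and replicate 2 held tissue pooled from 88. A total of 57449 peaks were listed for replicate 1 and 62846 for replicate 2. The pooled list, called on both replicates together, held 40274 peaks, and 35463 of these formed the replicated list. Read depth is unknown from the peak lists. With 1 group there was no contrast between conditions, so the comparisons below are between the replicates, between parts of the genome, and between groups of genes. Genes and peaks are not replicates, and each p describes these lists. A gene is called marked where a replicated peak overlapped the 1000 bp on either side of one of its transcription start sites (TSSs). Fold enrichment is the submitters' value for a peak, used to rank, filter, describe and compare peaks.

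Both replicates marked largely the same genes. Of 21938 protein-coding genes, 14370 had a peak at a TSS in replicate 1 and 14525 in replicate 2, and 14056 had one in both, which was 94.7% of the genes marked in either. The peaks themselves were shared less often. Of the replicate 1 peaks on the standard chromosomes, 59.4% overlapped a replicate 2 peak by at least 50% of either peak, against 2.15% ± 0.062 (SD) for 1000 random placements. Of the replicate 2 peaks, 46.6% overlapped a replicate 1 peak, against 1.93% ± 0.052 at random. Both shares lay above every random placement (one-sided permutation p = 0.001, the smallest that 1000 placements can give). With the 37801 peaks of lowest p from each replicate, the shares were 72.1% and 62.6%, and with an overlap of 50% of both peaks they were 39.4% and 36.0%. Across 23077 peaks in one-to-one overlap, fold enrichment had a Spearman's rho of 0.872 and a Pearson's r of 0.916 on the log2 scale. These are correlations across peaks, which are not independent replicates.

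The pooled peaks that the submitters kept as replicated were mostly at promoters, and were wider than those not kept. Of 35457 replicated peaks on the standard chromosomes, 56.0% had their midpoint within 1000 bp of a TSS, compared with 23.0% of the 4809 pooled peaks that were not kept (odds ratio 4.28). Median width was 593 bp for replicated peaks and 215 bp for the others, and median fold enrichment was 4.99 and 2.90. Mean log2 width differed by 1.45 and mean log2 fold enrichment by 1.11. No p is given for the differences in promoter share, width and fold enrichment, because the kept peaks were selected through both replicates' lists. That selection is not independent of width and strength, and promoter peaks were wider and stronger than other replicated peaks.

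Replicated peaks lay at promoters far more often than random positions did. Promoters held 19870 of the 35457 peaks (56.0%, 95% Wilson interval 55.5 to 56.6), which was 11.4 times the mean of 4.91% for random placements. Introns held 22.8% of the peaks against 39.2% at random, and intergenic sequence 16.8% against 52.6%. Exons held 4.41% against 3.28%. The promoter and intron shares were 42.3% and 31.7% in replicate 1 alone, 37.8% and 34.7% in replicate 2 alone, and 81.8% and 7.11% among peaks of at least the median fold enrichment, where intergenic sequence held 8.52%. Each class differed from random placement at a one-sided permutation p of 0.001, the smallest possible. Promoters were assigned first and the shares of the classes sum to the whole, so the promoter excess alone lowers the other shares. The intron, exon and intergenic differences are thus not separate results. These classes were not compared with random positions among peaks outside promoters only. The exon difference ended with a promoter window of 2500 bp (2.48%, permutation p = 0.428). It turned to a deficit, 2.56% of peaks, among peaks with a fold enrichment of at least the list's median, where promoters held 81.8%. Promoter peaks had a median width of 956 bp and a median fold enrichment of 9.17, and made up 73.1% of the covered bases. The 15587 peaks with a midpoint away from promoters had a median width of 361 bp and a median fold enrichment of 3.61.

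**Figure D1:**
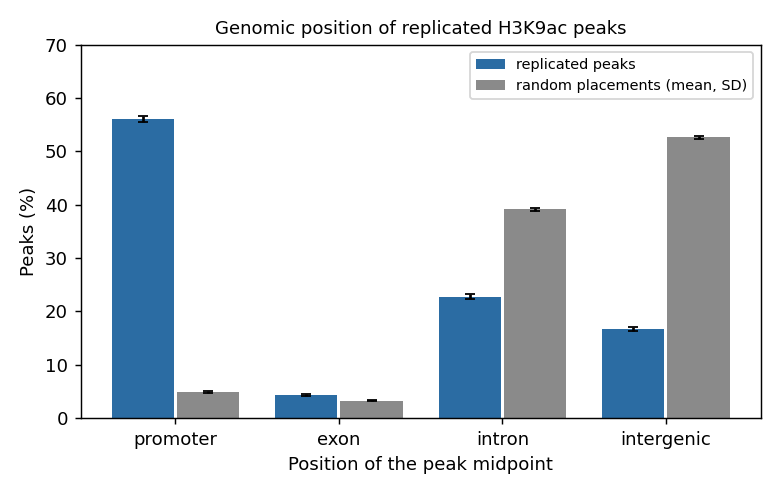
Share of replicated H3K9ac peaks (%, vertical axis) whose midpoint lay at a promoter, exon, intron or in intergenic sequence. Blue bars are the 35457 peaks with 95% Wilson intervals, grey bars are the mean of 1000 random placements with its SD, and promoters hold 56.0% of peaks against 4.91% at random.

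The replicated peak of highest fold enrichment, 49.8, lay on chromosome 7 from 73556618 to 73558610 (mm10) at the promoter of a long noncoding RNA gene, 15784 bp from the nearest protein-coding TSS, that of Chd2. The next 4 were a peak in an intron near the TSS of Bahcc1 (46.7) and promoter peaks of Lmnb1, which encodes lamin B1 (46.2), of Msi1, an RNA-binding protein of neural progenitors (45.7), and of Pcif1 (45.1). The 10 peaks of highest fold enrichment with a midpoint outside promoters included those at Sox4 (39.0) and Sox11 (37.5), transcription factor genes of neuronal differentiation. The midpoints of these peaks lay 1748 bp and 1014 bp from the TSS, but both peaks were broad enough to reach over it. Of the 10, the farthest from a protein-coding TSS lay 70715 bp from the TSS of Mef2c, a transcription factor gene. That peak spanned 21644 bp on chromosome 13, from 83712781 to 83734424, with its midpoint in an annotated exon and a fold enrichment of 36.3.

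Pan-forebrain, telencephalon and neural progenitor genes were marked nearly without exception. All 26 genes of the dorsal telencephalon list, all 22 of the ventral telencephalon list and all 22 of the neural progenitor list had a replicated peak at a TSS, as did 21 of 22 pan-forebrain transcription factors, compared with 64.1% (14060) of all 21938 protein-coding genes. Among pan-forebrain factors the highest fold enrichments were those of Lhx2 (32.8), Nr2f1 (32.8) and Pou3f3 (31.8). Foxg1, a regulator of telencephalon growth, had 28.9. Only Six6, an eye and hypothalamus regulator, had no replicated peak, although replicate 1 alone listed one there (3.56). The dorsal list was led by Emx2 (31.7), Gli3 (29.4) and Pax6 (26.1), and the ventral list by Sox6 (27.6), Zeb2 (27.0) and Ascl1 (16.7). Msi1 (45.7), Tead2 (36.6) and Sox2 (35.7), the last a factor that maintains neural stem cells, led the progenitors. Each of these 4 lists was marked more often than other genes (two-sided Fisher's exact test, Benjamini-Hochberg over 25 lists, adjusted p = 0.00154 for pan-forebrain, 4.08e-05 for dorsal, 0.000158 for ventral and 0.000158 for progenitor genes). Among other genes of like promoter CpG content, the expected shares were 84.1% for pan-forebrain, 87.2% for dorsal, 92.6% for ventral and 89.8% for progenitor genes. In an exact test over CpG deciles, the call held for dorsal genes (adjusted p = 0.0131). It ended for pan-forebrain (0.0849), ventral (0.25) and progenitor genes (0.0746), the last of which the approximate Mantel-Haenszel test still called (0.0456). All ventral and progenitor genes were marked, so no higher share was possible against expected shares of 92.6% and 89.8%. A call that ended there does not show that CpG content accounts for the marking. Among peaks of at least the median fold enrichment, dorsal genes lost their call against all other genes (20 of 26 marked, 76.9% against 58.2%, adjusted exact p = 0.0852).

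Neuronal genes were also marked, those of later maturation included. Of the early neuron list, 23 of 24 genes were marked (95.8%, adjusted exact p = 0.000649), led by Stmn1 (28.0), Elavl4 (23.0) and Mapt (15.5), which encodes tau, while Nhlh1 was not. Of the mature neuron and synapse list, 25 of 26 were marked (96.2%, adjusted exact p = 0.000426), led by the synaptic vesicle gene Vamp2 (28.4), Shank2 (15.1) and Dlg4 (13.2), and Sst, the somatostatin gene, was not. Shank2 had 7.20 in replicate 1 and 16.8 in replicate 2, and Dlg4 14.2 and 11.9, so their order differed between the replicates. The calls of both neuronal lists held at like CpG content of the outermost TSS (adjusted exact p = 0.00595 and 0.00609). The peak given for Shank2 lay at another TSS. Among peaks of at least the median fold enrichment the mature neuron list lost its call (18 of 26 marked, 69.2% against 58.2%, adjusted exact p = 0.335). By contrast, 7 of 20 astrocyte and oligodendrocyte genes were marked (35.0%, adjusted exact p = 0.0111), led by Slc1a2 (13.5), Mbp (11.2) and Cnp (6.72), and Aldoc, Aqp4 and Gfap were unmarked. That deficit ended at like CpG content (adjusted exact p = 0.258) and in replicate 1 alone (10 of 20 marked, 0.175).

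Genes that most cells use and signalling genes were marked throughout. All 36 signalling targets and ligands were marked. The highest fold enrichment, 31.4, was given to Fgfr2 for a peak at its farthest upstream annotated TSS that also lay at Ctbp2, while a peak at other TSSs of Fgfr2 had 19.5. Next were Axin2, a target of Wnt signalling (23.2), and Spry2, a target of fibroblast growth factor signalling (22.04). Also marked were all 28 cell cycle genes, led by Cdk4 (29.8), Cdk1 (27.0) and Rrm2 (26.3), all 25 housekeeping genes, led by Actb (43.8), Ywhaz (38.4) and Rpl13a (37.5), all 23 genes of the histone acetylation machinery, led by Ep300 (34.1), Kat2a (32.1) and Kat6b (28.2), and all 79 cytosolic ribosomal protein genes, led by Rps19 (39.0), Rpl13a (37.5) and Rpl32 (33.1). Adjusted p in Fisher's exact test was 1.01e-06, 1.62e-05, 6.38e-05, 0.000161 and 9.24e-15 in that order. At like CpG content the calls held for signalling (adjusted exact p = 0.00515) and ribosomal protein genes (0.00354) and ended for cell cycle (0.448), housekeeping (0.0746) and acetylation genes (0.203). Every gene of the lists that lost their call was marked, so no higher share was possible. Those losses do not show that CpG content accounts for the marking. Of 67 replication-dependent histone genes, 57 were marked (85.1%, adjusted exact p = 0.000301), led by Hist4h4 (25.7), Hist3h2a (25.6) and Hist1h2be (23.8), with Hist1h1d, Hist1h1t and Hist1h2aa unmarked, and at like CpG content the difference turned to a deficit of -8.15 points (0.0197). At 34 of the 57 marked histone genes the peak also lay at the TSS of another protein-coding gene, for Hist3h2a at Trim17 and for Hist1h2be at Hist1h1e. Imprinted genes were marked in 17 of 20 cases, led by Grb10 (19.02), Nnat (18.4, a peak also at Blcap) and Igf2r (17.5), with Kcnk9, Ndn and Rasgrf1 unmarked, and did not pass the test (adjusted exact p = 0.0697). They passed it in the pooled list (18 of 20, 0.0201), in replicate 1 alone (18 of 20, 0.0213), in replicate 2 alone (18 of 20, 0.0362) and with a promoter window of 2500 bp (19 of 20, adjusted exact p = 0.00436).

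The diencephalon, hypothalamus and eye field, which also belong to the forebrain, and more posterior regions were covered by 3 lists. The diencephalon, hypothalamus and eye field list was marked in 25 of 27 cases (92.6%, adjusted exact p = 0.00145), led by Tcf7l2 (25.9), Vax1 (19.7) and Lhx5 (13.0), with Crx and Vsx2 unmarked. Its expected share at like CpG content was 93.9% (adjusted exact p = 0.598), and among peaks of at least the median fold enrichment it was marked in 12 of 27 cases (44.4% against 58.2%, 0.188). The midbrain and hindbrain list was marked in 16 of 25 cases (64.0%, adjusted exact p = 1), led by Mafb (13.1), Phox2a (9.81) and Tal2 (8.22), and Fev, Foxa2 and Gata3 were unmarked. Genes of like CpG content were marked in 93.0% of cases, a difference of -29.0 points (adjusted exact p = 1.56e-05), and among peaks of at least the median fold enrichment 5 of 25 were marked against 58.2% of other genes (0.000244). Of 39 Hox genes, which pattern the hindbrain, spinal cord and trunk, 4 were marked (10.3%, 95% Wilson interval 4.06 to 23.6, adjusted exact p = 3.2e-11), against 89.7% expected at like CpG content (1.34e-40). The 4 were Hoxa7 (4.21), Hoxa4 (3.14), Hoxd13 (3.11) and, named after its value was seen, Hoxd8 (2.98). Hoxa4 was marked in the list of replicate 1 (4.85) but not in that of replicate 2. The peaks of the 4 genes covered 201 to 293 bp. In replicate 1 alone 7 were marked, and in the replicated list none had a peak of at least the median fold enrichment. Unmarked members included Hoxa1, Hoxa10 and Hoxa11.

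**Figure D2:**
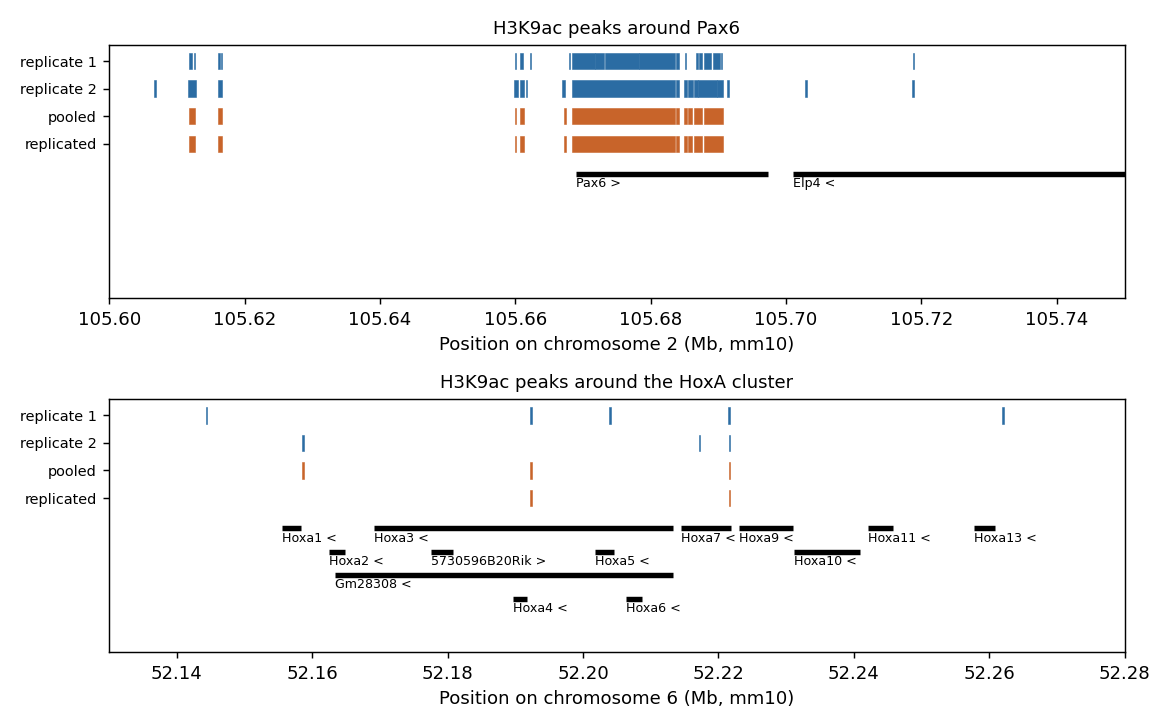
Peaks of the 4 lists (blue for the single replicates, orange for the pooled and replicated lists) over chromosome 2 around Pax6 and over chromosome 6 around the HoxA cluster, with position in Mb (mm10) on the horizontal axis and black bars for protein-coding genes. In windows of equal length the replicated list covers 23549 bp in 11 peaks around Pax6 and 536 bp in 2 peaks over the HoxA cluster.

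Genes of the liver, of heart and skeletal muscle, of endoderm and germ cells, and of olfactory receptors were marked less often than other genes. Of the liver list, 2 of 21 genes were marked (9.52%, adjusted exact p = 1.6e-06), Apoh (16.2) and Trf (4.25), and both peaks also lay at the TSS of another protein-coding gene, while Afp, Ahsg and Alb were unmarked. Of heart and skeletal muscle genes, 5 of 22 were marked (22.7%, adjusted exact p = 0.000263), led by Tnnc1 (21.1), Ckm (6.54) and Myh7 (6.40), with Acta1, Actc1 and Des unmarked. The peaks of Tnnc1 and Ckm lay at the TSSs of Nisch and Klc3 too. In the replicates' own lists Tnnc1 had 4.53 in replicate 1 and 23.8 in replicate 2, Ckm 4.10 and 8.35, and Myh7 3.79 and 6.07. Of endoderm and germ cell genes, 5 of 22 were marked (22.7%, adjusted exact p = 0.000263), led by Foxa3 (20.0), whose peak also lay at Sympk, and by Dazl (5.52) and Nkx3-1 (5.20), with Cdx1, Cdx2 and Ddx4 unmarked. Each of these 3 deficits held at like CpG content (adjusted exact p = 0.00595, 0.00667 and 1.37e-10). In replicate 2 alone 4 liver genes were marked, and in either replicate alone 8 muscle genes were, with all calls kept. Olfactory receptor genes were marked in 1 of 1135 cases, Olfr94 (7.11), with an adjusted exact p below 1e-300 against all other genes and of 5.58e-26 at like CpG content. In replicate 1 alone 4 were marked and in replicate 2 alone 5.

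Among blood and vessel genes, 5 of 19 erythroid genes were marked (26.3%, adjusted exact p = 0.00147), led by the erythroid transcription factor gene Klf1 (13.8), Gypa (6.79) and Nfe2 (5.80), with Alas2, Epb42 and Gata1 unmarked. Of microglia and myeloid genes, 2 of 20 were marked, Irf8 (5.10) and Tmem119 (3.40), with an adjusted exact p of 3.36e-06, and Adgre1, Aif1 and C1qa were not. Both deficits ended at like CpG content, where 24.8% and 28.8% were expected (adjusted exact p = 1 and 0.0804). In replicate 2 alone 8 erythroid genes were marked, which ended that call (adjusted exact p = 0.0551), and 5 myeloid genes (0.00038), of which list replicate 1 alone marked 4 (0.000144). Endothelium and pericyte genes were marked in 10 of 20 cases (adjusted exact p = 0.264), led by Kdr, the vascular endothelial growth factor receptor gene (8.64), Erg (6.79) and Pdgfrb (6.40), with Cdh5, Emcn and Eng unmarked, and differed from genes of like CpG content by -21.6 points (0.0197). They were also called less often marked at a −log10 q of at least 2 (7 of 20, adjusted exact p = 0.0201) and among peaks of at least the median fold enrichment (3 of 20, 0.000214). Mesenchyme and neural crest genes were marked in 17 of 23 cases (73.9%, adjusted exact p = 0.406), led by Prrx1 (15.4), Dlk1 (12.7) and Prrx2 (10.4), with Col3a1, Dcn and Foxd3 unmarked, but 21 of 23 were marked in replicate 1 alone (adjusted exact p = 0.00987). Over all lists with fixed names, 41 genes were marked in 1 replicate only, among them Aldoc and Csf1r in replicate 1 and Apoa1, Cd68 and Col3a1 in replicate 2.

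**Figure D3:**
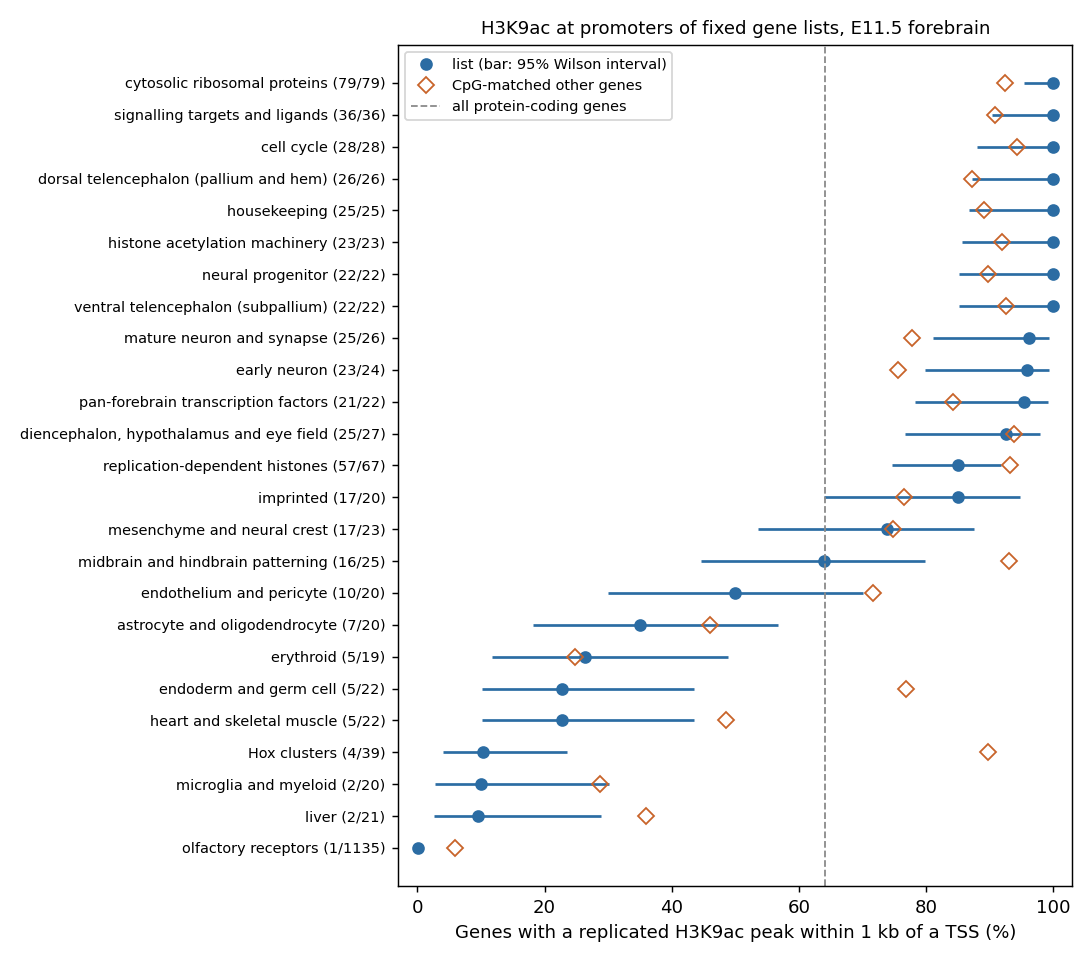
Share of genes with a replicated peak within 1000 bp of a TSS (%, horizontal axis) for each of the 25 gene lists, with marked and total members in brackets. Blue points are the lists with 95% Wilson intervals, open orange diamonds the share among other genes of like promoter CpG content, and the dashed line the 64.1% of all protein-coding genes, with Hox genes at 10.3% against 89.7% expected from CpG content.

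Of the gene lists tested, pan-forebrain factors had the highest median breadth. Marked pan-forebrain factors had a median of 8835 bp covered within 5000 bp on either side of the TSS, against 1701 bp for other marked genes, a mean difference of 2.02 on the log2 scale. Over 5000 bp were covered at 19 of the 21, compared with 301 of all 14060 marked genes (2.14%). The 10 most covered protein-coding genes were Lhx2, Msi1 and Pax6 (10001 bp each, the whole window), Zic2 (9921), Tnrc18 (9822), Zmynd8 (9759), Bahcc1 (9755), Meis2 (9737), Skida1 (9703) and Otx1 (9692). In the replicated list a single peak over the Pax6 promoter spanned 15246 bp, from 105668336 to 105683581 on chromosome 2. It covered the promoter and the 5′ part of the gene. Replicate 2 listed a single peak of 15264 bp there, but replicate 1 listed separate peaks of 3327, 1338, 5001 and 5295 bp. Progenitor genes (4902 bp, log2 difference 1.42), dorsal (3302 bp, 1.04) and ventral telencephalon genes (3171 bp, 0.93), signalling genes (4240 bp, 1.00), replication-dependent histones (3998 bp, 1.18), cell cycle (2780 bp, 0.78), ribosomal protein (2514 bp, 0.69), housekeeping (2897 bp, 0.62) and early neuron genes (2669 bp, 0.56) were also broader than other marked genes. Adjusted p in two-sided permutation tests was 2.33e-05, except for housekeeping (0.00103) and early neuron genes (0.00373). The same 10 lists were called broader in all 10 settings tried, matching on CpG content included. Because peaks of neighbouring genes count, a high value for the clustered histone genes need not be a broad domain. Hist1h1d, which was unmarked, had 4162 bp covered, and 34 of the 57 marked histone genes shared their peak with another protein-coding gene.

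Mature neuron genes, nearly all marked, did not pass the test of breadth against other marked genes (median 1324 bp, adjusted permutation p = 0.195), but were called narrower among peaks of at least the median fold enrichment (-0.43, 0.024). Midbrain and hindbrain genes had narrower acetylation (985 bp, log2 difference -1.06, adjusted permutation p = 2.33e-05), as had endothelium and pericyte genes (943 bp, -1.07, 0.000535) and the 5 marked endoderm and germ cell genes (471 bp, -1.72, 8.4e-05). The call of midbrain and hindbrain genes ended among peaks of at least the median fold enrichment (5 marked genes, -0.58, adjusted permutation p = 0.0979), where the other 2 lists, with 3 marked genes each, were not tested. Replicate 2 alone called 8 lists narrower and replicate 1 alone 7. Among these were erythroid genes in replicate 2 (-1.14, adjusted permutation p = 0.00204), muscle genes in replicate 1 (-0.80, 0.0224) and replicate 2 (-0.88, 0.013), and astrocyte and oligodendrocyte (-0.65, 0.0358) and mesenchyme genes (-0.45, 0.0358) in replicate 1. The difference of endoderm and germ cell genes was -0.89 in replicate 2 alone. Of the other lists with at least 5 marked genes, none passed the test in the replicated list against all other marked genes: diencephalon (1574 bp, adjusted permutation p = 0.516, but narrower at like CpG content by -0.44 with 0.00412), astrocyte and oligodendrocyte (1664 bp, 0.336), histone acetylation machinery (2084 bp, 0.126), imprinted (2239 bp, 0.449), erythroid (1214 bp, 0.312), mesenchyme (1529 bp, 0.971) and muscle genes (1328 bp, 0.533).

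**Figure D4:**
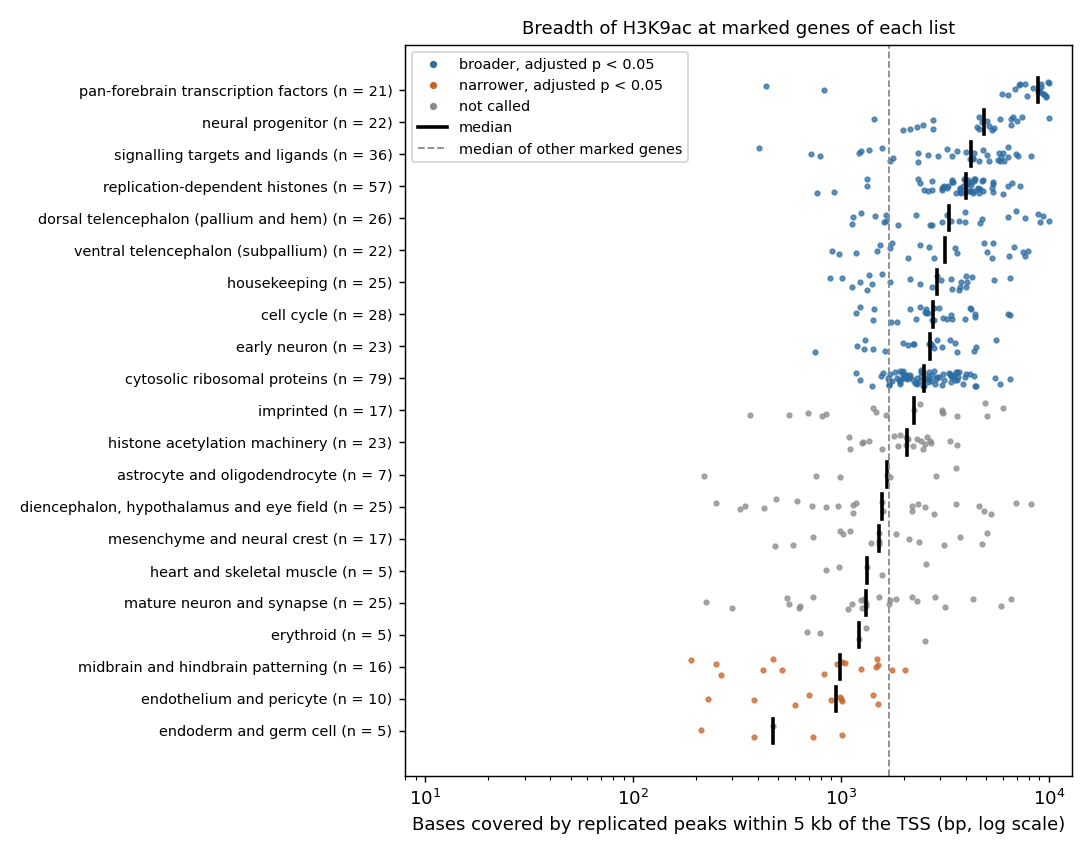
Bases covered by replicated peaks within 5000 bp on either side of the most covered TSS (bp, log scale, horizontal axis) for each marked gene (points) of the lists with at least 5 marked members. Black bars are list medians, the dashed line is the median of other marked genes, and colours give the permutation test, with pan-forebrain transcription factors at a median of 8835 bp.

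Forebrain, progenitor and signalling genes had more peaks with a midpoint away from promoters than expected. Such peaks within 5000 bp of a TSS count towards breadth as well, so the 2 measures overlap. The expectation here came from all protein-coding genes, marked or not, whereas breadth was compared among marked genes. Progenitor genes had a mean of 9.41 distal peaks nearest to them, against 1.31 expected from other genes with territories of like length (adjusted p = 8.33e-05 in a permutation test stratified by territory length). Pan-forebrain factors had 8.91 against 1.23 (8.33e-05), dorsal telencephalon genes 4.96 against 1.15 (0.003), signalling genes 4.78 against 1.25 (0.0011), ventral telencephalon genes 4.68 against 1.05 (0.00804) and diencephalon genes 3.63 against 1.28 (0.022). Progenitor genes had 13.55 against 2.73 in replicate 1 alone and 18.45 against 3.43 in replicate 2 alone, where distal peaks numbered 33141 and 39100 in place of 15587. Msi2 and Sox9 had 32 each, Nr2f2 26, Nr2f1 23 and Notch1 21. Histone (0.522 against 0.172, adjusted permutation p = 0.001) and ribosomal protein genes (0.899 against 0.421, 0.0311) had more as well, and olfactory receptor genes had fewer (0.0238 against 0.333, 8.33e-05). The other 16 lists did not pass the test in the replicated list, midbrain and hindbrain genes among them (2.16 against 1.07, adjusted permutation p = 0.0766). Cell cycle genes passed it with a promoter window of 500 bp (adjusted permutation p = 0.007), at a −log10 q of at least 2 (0.0417) and in replicate 1 alone (0.0195), and housekeeping genes with 500 bp (0.0395). Without strata of territory length, midbrain and hindbrain (adjusted permutation p = 0.0192), early neuron (0.0129), mesenchyme (0.0109) and imprinted genes (0.0311) passed it. With only peaks over 10000 bp from every TSS, 5 lists had more, and the calls ended for ventral telencephalon (adjusted permutation p = 0.0731), diencephalon (0.0858) and histone genes (0.0731). Fewer peaks are counted at that distance, so a call that ended does not show that the excess went away. The ratio to expectation for pan-forebrain factors was 7.27 in the replicated list, 4.54 in replicate 1 alone, 4.28 in replicate 2 alone, 4.16 over 10000 bp from every TSS and 13.8 among peaks of at least the median fold enrichment. That for histone genes was 3.03 in the replicated list, 1.92 in replicate 1 alone and 4.00 with a promoter window of 500 bp. Without strata the calls of histone (0.519, with a ratio of 0.735) and ribosomal protein genes (adjusted permutation p = 0.501) ended, the latter also among peaks of at least the median fold enrichment (0.136). That subset holds 8095 distal peaks in place of 15587, so the call lost there does not show that the excess went away.

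In 11429 distal peaks, 6 of 18 short sequence motifs were denser in the 500 bp around the peak midpoint than in the flanks and 7 were denser in the flanks (two-sided sign-flip permutation test, Benjamini-Hochberg over 18 motifs). Among those denser in peaks were GGGCGG of the SP/KLF family, with 0.844 per kb against 0.181 (4.66 times), the ETS motif CCGGAA (2.34 times), the E-box CAGCTG (1.62 times) and the SOX motif ACAAAG (1.25 times), each with an adjusted permutation p of 2.25e-05. The ratio of GGGCGG was 2.81 in replicate 1 alone and 2.85 in replicate 2 alone. CACGTG (1.26 times, 2.25e-05) and TGACGTCA (1.67 times, 0.00506) completed the 6. The homeodomain motif TAATTA was sparser in peaks, with 0.200 per kb against 0.275 (adjusted permutation p = 2.25e-05), as were CCAAT, AGATAA and TGACTCA (0.753, 0.726 and 0.848 times), CTTTGAT (0.873 times), CAGATG (0.944 times) and the SOX motif ACAATG (0.949 times). The calls of TGACTCA and CAGATG ended in either replicate alone, and those of CTTTGAT and ACAATG in replicate 2 alone (adjusted permutation p between 0.0826 and 0.952). GGAATG and TTGGCA were called denser in peaks in replicate 1 alone (adjusted permutation p = 0.000933 and 0.00155) and in replicate 2 alone (6e-05 and 0.0455), TTGGCA was called sparser among peaks of at least the median fold enrichment (0.00634), and GTTGCTA was called sparser in replicate 1 alone (0.0264). Peaks had a GC content of 52.8% and flanks 46.5%. In 2781 peaks matched to their flanks on GC content, CACGTG (1.14 times) and TGACGTCA (1.83 times) lost their calls. The ratio of CCGGAA was 1.32 and that of GGGCGG 2.15, and 1 motif, CCAAT, was denser in the flanks. TAATTA (1.33 times, adjusted permutation p = 0.00042) and ACAATG (1.22 times, 0.00018) turned to being denser in the peaks.

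Marked genes were unevenly spread over chromosomes. Of 948 protein-coding genes on the X chromosome, 451 were marked (47.6%, against 64.8% elsewhere, two-sided Fisher's exact test, Benjamini-Hochberg over 21 chromosomes, adjusted p = 2.36e-25), at 5.20 peaks per Mb. Of 183 genes on the Y chromosome, 3 were marked. Tissue of both sexes was pooled, and these shares take no account of the copy number of X and Y or of how uniquely reads map there. Chromosome 11 had the most peaks per Mb (24.99), and chromosome 12 the highest share of marked genes (78.1%, adjusted exact p = 5.37e-14). In all, 9 chromosomes had a higher and 6 a lower share than the rest. Shares on chromosomes 7 (52.8%, adjusted exact p = 7.67e-27) and 14 (53.4%, 7.88e-11) were among the lower ones. Without 1523 clustered receptor and keratin-associated genes, chromosome 2 turned from a lower share (61.7%, adjusted exact p = 0.0384) to a higher one (by 4.92 points, 0.00015). The difference of chromosome 7 was -12.4 points with these families and -3.18 without them (adjusted exact p = 0.018), the calls of chromosomes 3, 4, 5, 6 and 18 ended, and chromosomes 9 and 16 gained a higher share. In replicate 1 alone the call of chromosome 3 ended as well (adjusted exact p = 0.0872). In replicate 2 alone chromosome 1 gained a higher share (69.8% against 66.0% elsewhere, adjusted exact p = 0.0107).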

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

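Peaks outside the standard chromosomes took part in no comparison, and 6 replicated peaks lay there. They are listed because the signal lies in data that no comparison used. 3 were on an unplaced scaffold of the X chromosome, 2 on one of chromosome 4 and 1 on a scaffold with no chromosome. The highest fold enrichment among them was 15.4, in a peak of 1367 bp on the chromosome 4 scaffold. No explanation was tested.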

How the results depend on the processing

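All alternatives were planned except random positions outside assembly gaps and the exact test over CpG deciles, chosen after seeing the data. Of the 124 values that answer a comparison under an alternative, 112 kept their direction and side of the threshold, or stayed within 1.5 times a count. Spearman's rho of fold enrichment was 0.867 for pairs with any overlap and 0.882 for −log10 p. The exon share was 2.48% with a promoter window of 2500 bp, which takes peaks from the exon class. Among peaks with a fold enrichment of at least the median it was 2.56%, below random, with 81.8% of those peaks at promoters. With CpG matching 6 lists were marked more often by the Mantel-Haenszel and 5 by the exact test, and 3 were called so in all 11 settings: early neuron, signalling and ribosomal protein genes. Narrower lists numbered 1 among peaks of higher fold enrichment (mature neuron genes, with endothelium and endoderm genes untested) and 7 to 8 in single replicates. Over 10000 bp from every TSS, 5 lists had more distal peaks. Motifs denser in flanks numbered 1 with GC matching and 3 to 6 in single replicates. Where a value or the construction does not show it, the cause was not tested. No paired analysis was possible because there is 1 group.

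Of 810 values for single lists, motifs and chromosomes, 691 kept direction and call, 34 gained and 39 lost a call, and 46 changed sign. Changes of sign in marking, in points, were midbrain and hindbrain genes (2.80 with a 2500 bp window, 3.50 in the pooled list, -2.21 to 10.5 in single replicates), diencephalon (-13.8 at higher fold enrichment, -1.28 with CpG matching), erythroid (1.56), mesenchyme (-0.910) and histone genes (-8.15) with CpG matching, and mesenchyme genes with 1 TSS per gene (-3.80). For log2 breadth they were diencephalon (0.00733 with a 500 bp window, 0.42 at higher fold enrichment, 0.0368 to 0.0885 in single replicates), mesenchyme (0.00812 with 2500 bp, 0.13 with a breadth window of 10000 bp, -0.45 to 0.22 in single replicates), astrocyte and oligodendrocyte (0.0123 at a −log10 q of at least 2), muscle (0.14 with CpG matching) and erythroid genes (0.21 with 10000 bp). For distal peaks per gene they were astrocyte and oligodendrocyte (-0.000444) and myeloid genes (-0.0140) at higher fold enrichment, myeloid (-0.0605) and histone genes (-0.188) without strata, astrocyte and oligodendrocyte (-0.142) and Hox genes (0.0219) over 10000 bp from a TSS, and erythroid genes (-0.452 to 0.0504 in single replicates). For motifs per kb they were GTTGCTA (4.75e-05 with 1000 bp), TAATTA (0.0626), ACAATG (0.105), GTAAACA (0.0194), CTATTTATAG (-0.000360) and CTTTGAT (0.00863) with GC matching, and in single replicates CAGATG (0.000617 to 0.0164), GTAAACA (-0.00678 to 0.00377) and TTGGCA (0.0164 to 0.0266). For chromosomes, in points, they were 17 in single replicates (-0.369 to 0.779) and, without the clustered families, 1 (-0.732), 2 (4.92), 3 (-0.647) and 17 (1.10). Depth limits what can be said of unmarked genes, since it is unknown.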

Other observations

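Of 13374 long noncoding RNA (lncRNA) genes, 2973 had a replicated peak within 1000 bp of a TSS (22.2%), and of the 9507 whose TSSs all lay more than 5000 bp from every protein-coding TSS, 823 had one (8.66%). The share of marked protein-coding genes rose with promoter CpG content over the deciles. In the decile of lowest content, 1.87% of 2194 genes were marked, in the fifth 81.5%, and in the highest 98.4%. Among marked genes, the median covered length was 1344 bp in the lowest decile, 1045 bp in the fourth and 2470 bp in the highest. None of the 8 globin genes of the erythroid list was marked, while Klf1, a transcription factor gene of red blood cells, was marked at a fold enrichment of 13.8.

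The replicated list and the replicates' own lists did not name the same genes throughout. 132 genes were marked in both replicates but not in the replicated list, and 136 were marked in the replicated list but not in both replicates, beside 13924 marked in all 3. Among the first kind were Hist1h1d, with 3.56 in replicate 1 and 22.3 in replicate 2, and Wnt1, named after its values were seen, with 3.56 and 3.13. Of the replicated peaks, 86.4% overlapped a peak of both replicates by at least 1 bp. Of the other 4824, 4063 lacked a peak in replicate 1 only, 750 in replicate 2 only and 11 in both, and their median fold enrichment was 3.21, against 5.92 for those found in both.

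The tests on peaks that the pooled list lacks and the exact test over CpG deciles were chosen after the result was seen, and the other tests below were set before it. A first hypothesis was that acetylation at promoters lies over the first transcribed nucleosomes. It was tested at marked genes with 1 annotated TSS and no other gene's TSS within 5000 bp. The summit of the strongest promoter peak lay downstream of the TSS at 762 of 874 genes (87.2%, 95% Wilson interval 84.8 to 89.2, exact binomial p = 1.56e-119), with a median offset of 223 bp. The share was 86.3% in replicate 1 and 82.8% in replicate 2. These values are consistent with the hypothesis for such genes, and nucleosome positions were not measured.

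The pan-forebrain, telencephalon and progenitor lists were marked more often than other genes, and their CpG-rich promoters are a candidate explanation. The diencephalon, hypothalamus and eye field list, also of the forebrain, was not part of this set. It too was marked more often than other genes, but showed no excess at like CpG content. Together the 4 lists (pan-forebrain, dorsal, ventral and progenitor) held 92 genes, of which 91 were marked (98.9%), against 63.9% of other genes and 88.4% expected at like CpG content. The Mantel-Haenszel odds ratio over CpG deciles was 11.2 (95% confidence interval 1.97 to 63.4, or 4.30 to 1328 by the exact conditional method, exact p = 3.7e-06). CpG content at the gene's outermost TSS thus does not account for the whole difference. Marking could rest on any TSS, and the peaks given for Notch1, Nr2f2, Lhx2, Sox6 and Zeb2 lay at other TSSs. For how many of the 92 genes this holds was not counted. CpG content at the marked TSS was not matched, so it stays open as an explanation. The intervals are wide because 1 gene of the 92 was unmarked, and of the 4 lists alone only the dorsal one passed the exact test, a list that lost its call against all other genes among peaks of at least the median fold enrichment. In the ventral and progenitor lists all genes were marked, so no higher share was possible there. No biological explanation was tested, since the design has 1 group, and the lists' own identity stays open as a hypothesis.

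Motifs denser in distal peaks than in their flanks could come from the higher GC content of the peaks. Of the 6 motifs, 4 kept an adjusted p under 0.05 and a higher density in peaks matched to their flanks on GC content (49.4% against 48.5% after matching). This argues against GC content as the whole cause for CAGCTG, CCGGAA and GGGCGG. The fourth, ACAAAG, holds mostly A and T, so a higher GC content would by itself make it sparser in peaks, not denser. That it kept its call (1.25 times before, 1.39 after) was thus no test of GC content as its cause. CpG content was not matched, and CCGGAA and GGGCGG each hold a CpG, so for both of these CpG content stays open. In the matched set the ratios of GGGCGG (2.15 against 4.66), CCGGAA (1.32 against 2.34) and CAGCTG (1.19 against 1.62) were lower, but that set also holds other peaks, with 0.418 GGGCGG per kb against 0.844, so what lowered them was not separated. For CACGTG (1.26 before, 1.14 after, adjusted permutation p = 0.243) and TGACGTCA (1.67 before, 1.83 after, adjusted p = 0.338) the matched set held 2781 of 11429 peaks, and GC content stays open. No biological explanation was tested.

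The replicates' own lists were longer than the pooled list, although the pooled list was called on both together. Of the replicate 1 peaks, 20344 (35.4%) overlapped no pooled peak, and of the replicate 2 peaks, 25781 (41.0%), and only 5.01% and 3.89% of these overlapped a peak of the other replicate (2.23% and 1.85% at random). Calls at random positions cannot be the whole cause, since 13.3% and 15.1% of these peaks lay at promoters, against at most 5.52% and 5.36% in 1000 random placements. Enrichment near the caller's threshold stays open. Only 0.0688% and 0.0310% of them had a −log10 p above the median of the peaks that overlapped a pooled peak, which does not measure nearness to a threshold, their median −log10 p was 4.09 and 4.28 against lowest values of 2.03 in each list, and 32.6% and 58.2% had a −log10 q of at least 2. Background specific to a library, or different thresholds for the lists, were not tested, and neither was a biological explanation.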
